A study of Mus musculus with 6 samples.

How the data were processed

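RNA of sorted mouse leukemia cells was measured by sequencing in 6 libraries, 3 from vehicle-treated and 3 from panobinostat-treated mice. Per the labels' protocols, RNA was isolated from the sorted spleen cells with an organic reagent and spin columns, and libraries were made with the Illumina TruSeq RNA kit from 1 ug of total RNA. The deposited values are whole-number read counts per gene, 1 column per library, with genes given by Entrez gene ID. Per the submitters' processing notes, the authors used bcl2fastq 2.17.1.14, FastQC 0.11.6, cutadapt 2.1, HISAT2 2.1.0, featureCounts from Subread 2.0.0 and limma, with the mouse build mm10. The gene annotation, the strand setting and the handling of reads with several placements are not given in the sources used here. Without a known strand setting, reads of overlapping or antisense genes cannot be separated, and near-identical genes (adult globin copies, Tgtp1 and Tgtp2, Oas1a and Oas1g, Ifit3 and Ifit3b) may share reads.

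The table held 27179 genes. Names came from RefSeq for the assembly GRCm38, the assembly that mm10 represents, by Entrez gene ID for 25275 genes and from GENCODE for 18 genes, and 1886 IDs stayed without a name. Positions are those of the RefSeq table. Each column was tied to its group by the word treated or control in its name. The names do not tie a column to a numbered replicate, so libraries carry the leading number of their column, and 0 columns were left unused. No row was matched to a mitochondrially encoded gene, so the 13 genes of that list and the mitochondrial share of counts were not analysed here, and neither were Hbb-bt and Ahsp of the erythroid list.

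Genes with low counts were removed with edgeR's filterByExpr by group, which left 12916, and libraries were scaled by TMM factors. Panobinostat was compared with vehicle by edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) with treatment as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, and the common biological coefficient of variation was 0.195. Fold changes are edgeR's log2 values, and their standard errors were approximated as the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM computed here. Binomial intervals and the value of a single count cover counting error only, and with 3 libraries per group an exact permutation test cannot give a p under 0.1.

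Before the data were examined, 33 gene lists were fixed, 8 of them primary and 10 of them markers of other cells that a spleen sort could hold. Of their 743 entries 728 were found and 561 were abundant enough to test. Lists with at least 3 tested genes, 30 in all, were tested with camera of limma 3.58.1 on voom values, 2-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside each list stand the calls over all genes, the calls adjusted over the list alone and the camera p with the correlation estimated from the data, under which no list passed. Neither camera version changes the calls of single genes. Some genes stand in more than 1 list, such as Bax, Bbc3, Btg2, Gata2 and Tubb3.

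Named genes followed a rule fixed at the same time. It took the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean of at least 5 CPM and non-overlapping groups, without predicted or unnamed genes. It took up to 4 called members with the smallest p from each primary list, and up to 2 from each other list with at least 3 called members. Always taken were genes including Hdac1, Hdac2, Hdac3, Hdac6, Runx1, Runx1t1, Nras, Ifnar1, Ifnar2, Irf7, Kit, Myc, Cdkn1a and Itgam. Other genes are said to be chosen after their values were seen.

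The test was checked on simulated counts for the 12916 genes of this comparison, drawn from the means and library sizes of these libraries. It recovered 65.7% of genes changed 2-fold, 95.5% of genes changed 2.83-fold and 95.5% of genes changed 4-fold. Of its calls 5.52% were false, 0 of 20 lists of unchanged genes were called, and a shifted list was called. Few genes were changed, evenly up and down, none at the lowest levels and none by less than 2-fold. These rates therefore do not cover smaller changes, genes near the floor or changes in a large share of genes. Genes were drawn independently of each other, so the 0 of 20 does not cover lists whose genes vary together, as in these libraries. Alternatives covered DESeq2 1.42.0, limma-voom with and without sample quality weights, robust dispersion shrinkage, 3 other normalizations, 2 other filters, the fry test and an estimated correlation for lists, and leaving out each of the 6 libraries. A fit without globin genes was added after the data were seen.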

Results

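The series profiled RNA from a mouse acute myeloid leukemia that the labels call A/E9a;NRASG12D, a name that joins a spliced form of the RUNX1-RUNX1T1 fusion with a mutant NRAS. C57BL/6 mice received either vehicle or panobinostat, a drug that inhibits histone deacetylases, for 3 days. GFP-positive, viable leukemia cells were then sorted from the spleen, with 3 libraries per group. The series title asks about plasmacytoid dendritic cells and differentiation of the leukemia through the type I interferon receptor, and the libraries described here are those of the leukemia cells themselves. The labels do not state that the 3 libraries of a group came from separate animals, so every p-value below measures only the spread between these libraries, which may be technical.

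Total counts were 29548544, 27259492 and 28338952 in vehicle libraries 2, 3 and 4, and 32571961, 25794869 and 32111154 in panobinostat libraries 1, 5 and 6. These numbers are the leading numbers of the count columns, which name the group but no replicate. The columns carry a further pair of numbers whose meaning is not given in the sources used here; vehicle libraries 2 and 3 share the same pair, and panobinostat library 1 differs from all other libraries in the last number. The first of the pair is shared by panobinostat libraries 1 and 6 and by no libraries of different groups, so if it marks a cage or batch it cannot be told apart from treatment. A single count was worth 0.0307 to 0.0388 CPM, the usual count scaled by library size. Between 16077 and 16626 genes had at least 1 count in a library, and 12916 were tested. No pair of libraries was a duplicate, since counts differed beyond sampling noise in all of them, with a chi-square per degree of freedom of at least 14.0. The first principal component held 58.5% of the variance and separated the groups. The next held 27.3% and ran from panobinostat library 1 at -46.95 to panobinostat library 5 at 35.6, so the treated libraries were less alike than the vehicle libraries.

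Vehicle leukemia cells carried erythroid, mast cell and progenitor transcripts together and little RNA of mature myeloid cells. Car2, a carbonic anhydrase of red cell precursors, was at 2282 ± 293 CPM (SD, n = 3), and Hdc, the enzyme that makes histamine, at 1230 ± 102 CPM. Ms4a2, a chain of the IgE receptor, was at 426 ± 58.6 CPM, and Gata1, the erythroid and megakaryocyte transcription factor, at 254 ± 7.84 CPM. Lysozyme (Lyz2) was at 2.38 ± 0.829 CPM and Ptprc, the pan-leukocyte antigen CD45, at 2.75 ± 0.554 CPM. These 6 genes were chosen after their values were seen.

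The main comparison asked which transcripts of the leukemia cells differed after panobinostat. Interferon-stimulated genes rose together, up to 39.4-fold for Ifit1 (19.9-fold without panobinostat library 1), and genes of MHC class I presentation rose with them. Adult and embryonic globin genes, megakaryocyte genes and a set of p53 target genes also rose. Genes of the S and G2/M phases of the cell cycle and of ribosome biogenesis fell, most of them by less than 2-fold. Of 12916 genes, 2715 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, 1460 of them higher and 1255 lower with panobinostat. A change of at least 2-fold was called in 830 genes, 637 higher and 193 lower, and these were 307 without vehicle library 4 and 337 without vehicle library 2. Over all tested genes, the 3 panobinostat values lay on one side of the 3 vehicle values in 5763 (44.6%), against 10% expected by chance. The number of calls was sensitive to single libraries and fell to 438 without vehicle library 4, 609 without vehicle library 2, 1259 without vehicle library 3 and 1637 without panobinostat library 5. Scaling by library size alone gave 1135 higher and 2065 lower genes, a share of 35.5% higher against 53.8% with the composition factors used here, and shifted the median log2 fold change of all genes from 0.01 to -0.10. Of the gene lists, limma's camera called 15 with its preset correlation, and from 10 to 18 in the other splits of the 6 libraries. Those splits still hold part of the treatment difference.

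Among the 10 genes with the largest increases under the naming rule (called, mean of at least 5 CPM) were embryonic globins, interferon-stimulated genes and regulators of early blood cells. Hbb-y, an embryonic beta-like globin (Entrez gene 15135; GRCm38 chromosome 7, 103851754 to 103853207), went from 5.55 ± 2.81 to 353 ± 213 CPM (SD, n = 3 each). Hbb-bh1, another embryonic globin, rose from 6.39 ± 2.59 to 136 ± 34.3 CPM. Ifit1, an antiviral effector (Entrez gene 15957; chromosome 19, 34640889 to 34650009), rose from 3.74 ± 0.846 to 148 ± 128 CPM, with Ifit1bl2 beside it and the oligoadenylate synthetase-like gene Oasl2 18.1-fold higher. Meis1, a homeobox factor of stem cells and leukemia (Entrez gene 17268; chromosome 11, 18880428 to 19019651), rose from 0.955 ± 0.683 to 19.6 ± 15.1 CPM. Id2, an inhibitor of helix-loop-helix transcription factors, rose 19.5-fold and Slamf1, a surface receptor of stem cells and lymphocytes, 18.3-fold. Notch3, a Notch receptor, and Map1a, a microtubule-associated protein best known from neurons, rose from means under 0.4 CPM to 10.9 ± 7.92 and 13.3 ± 14.1 CPM. Adjusted p from edgeR's quasi-likelihood test lay between 0.0014 for Hbb-bh1 and 0.014 for Map1a in these 10 genes. Meis1, Map1a and Slamf1 missed the threshold without vehicle library 2 or vehicle library 4 (edgeR adjusted p from 0.054 to 0.071), and Map1a also with limma-voom (0.062). Without panobinostat library 1 the folds were 19.9 for Ifit1, 12.1 for Ifit1bl2 and 10.3 for Oasl2. Without panobinostat library 5 they were 41.7 for Hbb-y, 38.1 for Notch3, 14.2 for Map1a, 11.5 for Meis1 and Id2 and 9.65 for Slamf1, and without vehicle library 3 they were 34.4 for Meis1 and 124 for Notch3.

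The 10 largest decreases among called genes with a mean of at least 5 CPM belonged to varied functions. Capn6, a calpain-like protein (Entrez gene 12338; chromosome X, 143802236 to 143827412), was at 20.6 ± 1.69 CPM in vehicle (SD, n = 3 each) and 12.8-fold lower with panobinostat. Cited1, a transcriptional co-activator (Entrez gene 12705; chromosome X, 102247378 to 102252181), fell 7.82-fold to 1.91 ± 0.338 CPM. Far2, a reductase that makes fatty alcohols, fell from 97.2 ± 5.87 to 19.2 ± 5.74 CPM, and Antxr1, an anthrax toxin receptor, from 72.9 ± 8.57 to 11.8 ± 6.13 CPM. Pkp1 of cell junctions, the protease inhibitor Spink2, Mamdc2, the kinesin Kif26b, the small GTPase Rhoj and the inhibitory receptor Pilra were 5.16-fold to 7.47-fold lower. Adjusted p from edgeR's quasi-likelihood test ranged from 0.0014 for Cited1 to 0.018 for Spink2. Calls were lost without vehicle library 2 for Pkp1, Spink2, Kif26b and Pilra (edgeR adjusted p from 0.053 to 0.063), without vehicle library 4 for the last 3 of these (0.062 to 0.070) and without vehicle library 3 for Spink2 (0.053). Capn6 was 20.3-fold lower without panobinostat library 6, and Pilra 7.86-fold lower without panobinostat library 5.

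**Figure D1:**
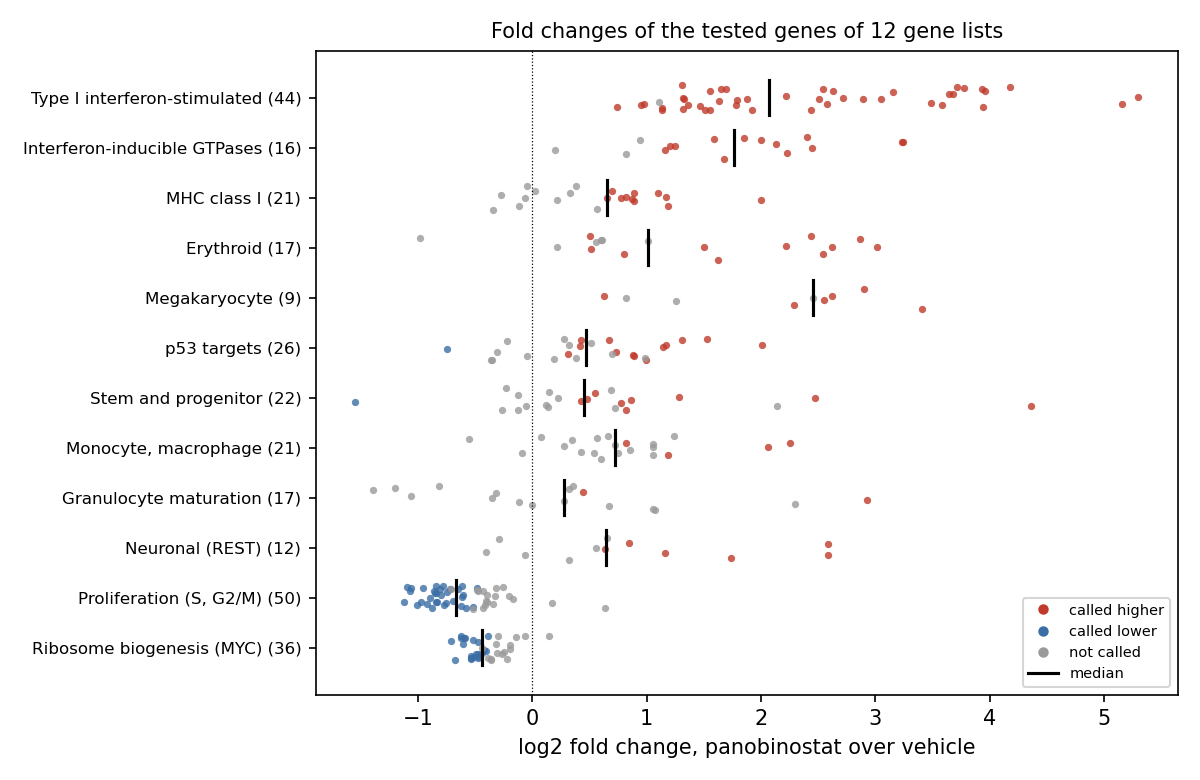
Log2 fold change of panobinostat over vehicle (horizontal axis) for each tested gene of 12 gene lists (vertical axis, number of tested genes in brackets), with red for genes called higher, blue for genes called lower, grey for genes not called and a black bar at the median. The interferon-stimulated genes lie to the right, with a median of 2.07, and the proliferation and ribosome biogenesis genes to the left, with medians of -0.67 and -0.44.

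Among the fixed lists, the type I interferon-stimulated genes had the highest share of called members. Of 44 tested type I interferon-stimulated genes 43 rose, by 0.74 to 5.30 on the log2 scale, and 44 passed when adjusted over the list alone. Ifi204 was the member that missed the threshold over all genes (2.15-fold, edgeR adjusted p = 0.088). Irf7, the transcription factor that amplifies the interferon response (Entrez gene 54123; chromosome 7, 141263183 to 141266499), rose from 24.0 ± 1.99 to 307 ± 149 CPM (SD, n = 3 each). Further members were the schlafen gene Slfn5 (log2 fold change 3.94 ± 0.24 SE), Ddx58, which encodes the RNA sensor RIG-I (2.54 ± 0.17), the oligoadenylate synthetase Oas3 (2.58 ± 0.19) and Samd9l, a growth-restraining antiviral gene (1.56 ± 0.11). All 4 had an adjusted p of 0.0013 or 0.0014 in edgeR's quasi-likelihood test. The list was called by camera (adjusted p = 2.7e-27) and not with an estimated correlation between its genes (adjusted p = 0.44 with an estimated correlation). Between 35 and 44 members were called when any 1 library was left out. Panobinostat library 1 changed most of the treated libraries in 38 of the 43 called genes, and it also had the highest share of hemoglobin counts, 6.72%. Red pulp macrophage markers, described with those of other cells, were also called higher by camera, and that call was lost without panobinostat library 1 (adjusted p = 0.22).

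Genes induced by interferon gamma moved the same way. Of 16 tested interferon-inducible GTPases and linked genes 13 rose, and 14 passed when adjusted over the list alone. The T cell-specific GTPases Tgtp1 and Tgtp2, near-identical copies whose reads cannot be assigned with certainty, rose by 3.25 ± 0.24 and 3.24 ± 0.23 (log2, SE, n = 3 each), both with an edgeR adjusted p of 0.0014. The list was called by camera (adjusted p = 2.3e-10; adjusted p = 0.44 with an estimated correlation). For the receptors, Ifnar1, a chain of the type I interferon receptor, rose from 54.6 ± 2.71 to 75.9 ± 10.3 CPM with an edgeR adjusted p of 0.030, a call that was lost without any 1 of vehicle libraries 2, 3 and 4 or panobinostat library 5 (0.062 to 0.13). Ifnar2, the other chain, was at 59.6 ± 10.1 CPM with panobinostat, a log2 difference of 0.34 ± 0.13 (SE) from vehicle, and did not pass (edgeR adjusted p = 0.098). Interferon receptor and interferon genes held 6 tested members, of which Ifnar1 alone was called, 3 were higher and 1 lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.18). The interferon genes Ifnb1, Ifng, Ifna1 and Ifna5 had 0 counts in all 6 libraries, and no other interferon gene of the list had more than 3 counts in total.

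MHC class I presentation rose with the interferon-stimulated genes. Of 21 tested genes 11 rose, and 14 were higher and 2 lower when adjusted over the list alone. Tapbp, the tapasin that loads peptide onto class I, went from 151 ± 1.77 to 345 ± 62.7 CPM (SD, n = 3 each), and B2m, the class I light chain, from 277 ± 23.1 to 624 ± 102 CPM. The nonclassical class I gene H2-T23 rose 2.14-fold and the peptide transporter gene Tap1 1.85-fold. Adjusted p from edgeR's quasi-likelihood test lay between 0.0042 and 0.0067 for these 4 genes. The list was called by camera (adjusted p = 1.1e-4; adjusted p = 0.44 with an estimated correlation), and 6 members were called without vehicle library 4 and 7 without vehicle library 2. All 11 tested MHC class II genes had a positive log2 fold change (median 0.99). Of these, 3 were called higher, and 4 passed when adjusted over the list alone. H2-Ob and H2-DMa, which encode chains of proteins that regulate peptide loading, rose from 2.16 ± 0.528 to 13.4 ± 4.59 CPM and from 0.569 ± 0.202 to 1.94 ± 0.999 CPM (edgeR adjusted p = 0.0043 and 0.034), and the call of H2-DMa was lost without any 1 vehicle library (0.060 to 0.13). The third was H2-Oa, named after its value was seen. The class II list was called by camera (adjusted p = 0.0089; adjusted p = 0.44 with an estimated correlation), and its adjusted p was 0.098 without panobinostat library 1.

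**Figure D2:**
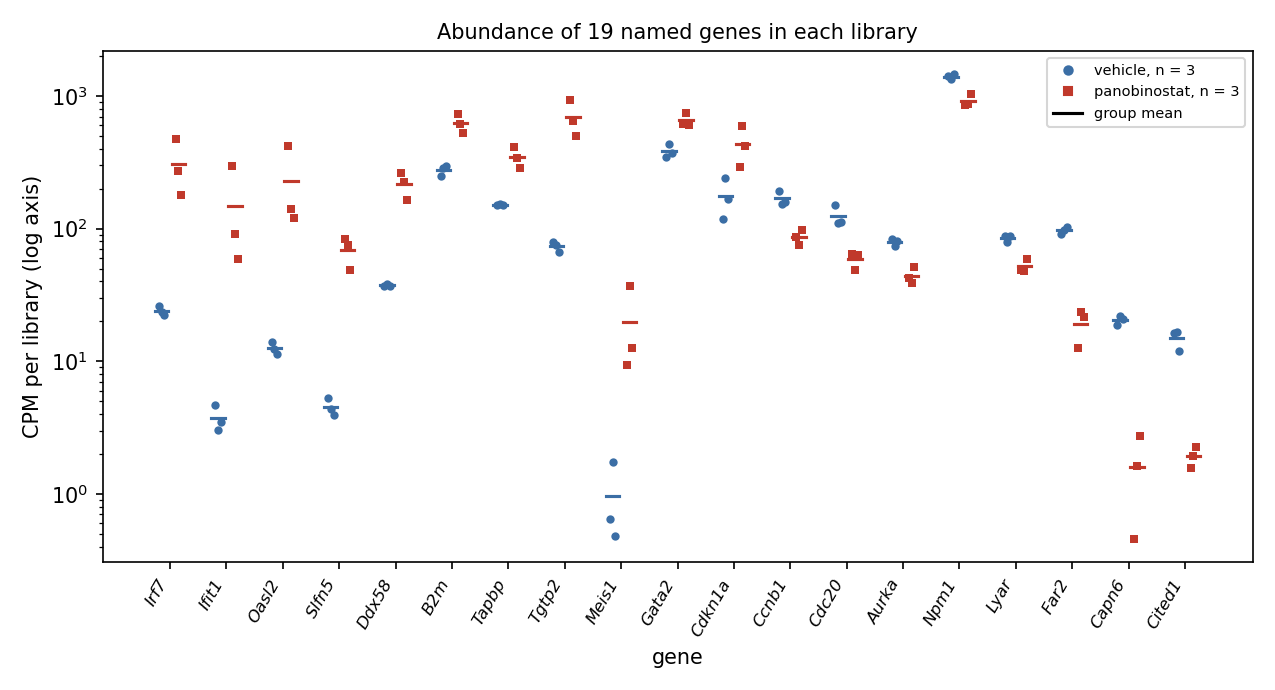
CPM per library on a log axis for 19 named genes, with vehicle libraries as blue circles, panobinostat libraries as red squares (n = 3 each, libraries in column order from left to right) and bars at the group means. The symbols of the groups do not overlap for any of these genes, with Irf7 at 179.7 to 471 CPM against 22.2 to 26.2 CPM and Ccnb1 at 74.6 to 97.9 CPM against 153 to 193 CPM.

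Cell cycle genes fell. Of 50 tested genes of the S and G2/M phases 32 fell and 0 rose, and 41 were lower when adjusted over the list alone. Ccnb1, the mitotic cyclin B1 (Entrez gene 268697; chromosome 13, 100778739 to 100786486), went from 169 ± 21.2 to 86.1 ± 11.6 CPM (SD, n = 3 each). Cdc20, which activates the anaphase-promoting complex, went from 124 ± 21.8 to 59.1 ± 8.88 CPM. The mitotic kinase gene Aurka and Ube2c, a ubiquitin-conjugating enzyme of mitosis, were both 1.79-fold lower, and all 4 genes had an edgeR adjusted p between 0.0065 and 0.0079. The list was called by camera (adjusted p = 2.6e-15; adjusted p = 0.44 with an estimated correlation), with 8 members called without vehicle library 2 and 8 without vehicle library 4. Panobinostat library 5 changed most in 23 of the 32 called genes and library 1 in 9.

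Genes of ribosome biogenesis that are linked to MYC fell as well, 21 of 36 over all genes and 29 when adjusted over the list alone, and 0 rose. Npm1, the nucleolar protein nucleophosmin, went from 1401 ± 61.0 to 921 ± 107 CPM (SD, n = 3 each). Lyar, Bop1 and Rrp9, which act in ribosomal RNA processing or in the nucleolus, were 1.63-fold, 1.43-fold and 1.60-fold lower, with edgeR adjusted p values between 0.0092 and 0.014 for the 4 genes. Camera called the list (adjusted p = 3.2e-11; adjusted p = 0.44 with an estimated correlation). The count of called members fell to 0 without vehicle library 4, 1 without vehicle library 2, and 9 without vehicle library 3 or without panobinostat library 5. Panobinostat library 5 changed most in 14 of the 21 called genes and library 1 in 7. All 4 named genes missed the threshold without vehicle library 4 (edgeR adjusted p from 0.057 to 0.074), as did Bop1, Rrp9 and Npm1 without vehicle library 2 (0.051 to 0.060). Myc itself was at 264 ± 24.0 and 225 ± 18.1 CPM and did not pass (edgeR adjusted p = 0.16; 0.048 with library size alone). The 40 tested cytosolic ribosomal protein genes held 0 called members over all genes and 0 when adjusted over the list alone in edgeR, with 1 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (camera adjusted p = 0.59), but the list was called lower without panobinostat library 1 (adjusted p = 0.0085).

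Of 26 tested p53 target genes 13 rose and 1 fell, and 14 were higher and 1 lower when adjusted over the list alone. Sesn1, a stress-induced sestrin, and Btg2, an antiproliferative factor, rose 1.66-fold and 2.20-fold (n = 3 each; edgeR adjusted p = 0.0066 and 0.0075). Cdkn1a, the cell cycle inhibitor p21, went from 176 ± 61.6 to 435 ± 155 CPM with an edgeR adjusted p of 0.031, a call that was lost without vehicle library 2, vehicle library 4, panobinostat library 5 or panobinostat library 6 (0.064 to 0.12). The member that fell was Ckap2, a protein of the mitotic spindle, named here after its value was seen. Panobinostat library 5 changed most in 13 of the 14 called genes. Camera called the list (adjusted p = 9.2e-4; adjusted p = 0.44 with an estimated correlation), with 2 members called without vehicle library 4, 3 without vehicle library 2, 8 without panobinostat library 5, and 9 without vehicle library 3 or without panobinostat library 6. Of 13 tested BCL2 family genes 4 rose and 7 passed when adjusted over the list alone. Both the death agonist Bid (0.73 ± 0.10) and the survival gene Bcl2l1 (1.06 ± 0.17) were among them, with edgeR adjusted p values of 0.0068 and 0.0090, and Bcl2l1 missed the threshold without vehicle library 2 (0.053) or 4 (0.056). Bmf and Bbc3, both death agonists and named after their values were seen, were the others. That list was called by camera (adjusted p = 0.013; adjusted p = 0.44 with an estimated correlation).

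Of 17 tested granulocyte maturation genes 2 rose, with 1 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.56). The chemokine receptor Cxcr2 was at 0.0927 ± 0.0755 and 0.738 ± 0.584 CPM (SD, n = 3 each; edgeR adjusted p = 0.038), a call that was lost without any 1 vehicle library or panobinostat library 5 (0.057 to 0.14); its fold of 7.62 was 13.4 without vehicle library 3 and 4.25 without panobinostat library 5. Itgam, the myeloid integrin CD11b, was at 0.296 ± 0.0923 and 0.360 ± 0.154 CPM, 6 to 15 counts per library, and did not pass (edgeR adjusted p = 0.71). Of 21 tested monocyte and macrophage genes 19 had a positive log2 fold change (median 0.73) and 4 rose, with 4 when adjusted over the list alone. Ctsd, a lysosomal protease, went from 360 ± 21.2 to 638 ± 143 CPM, and Ccr2, a chemokine receptor, from 9.01 ± 0.757 to 20.5 ± 7.84 CPM (edgeR adjusted p = 0.015 and 0.024). The high-affinity IgG receptor Fcgr1 and the transcription factor Maf rose 4.78-fold and 4.18-fold. All 4 missed the threshold without vehicle library 2 or 4 (edgeR adjusted p from 0.056 to 0.098), Maf and Ccr2 also without vehicle library 3 (0.056 and 0.060), Maf without panobinostat library 5 (0.058) and Ccr2 without panobinostat library 6 (0.050). Camera called the monocyte list (adjusted p = 0.0089; adjusted p = 0.44 with an estimated correlation). Of 11 tested primary granule and promyelocyte genes 2 rose, Plac8 and Cd63, both from means under 0.6 CPM and both named after their values were seen, and 3 passed when adjusted over the list alone (camera adjusted p = 0.11; 0.042 without panobinostat library 1).

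Stem and progenitor genes rose more often than they fell. Of 22 tested genes 9 rose and 1 fell, and 11 were higher and 1 lower when adjusted over the list alone. Besides Meis1, Adgrg1, an adhesion receptor of stem cells, went from 345 ± 29.0 to 839 ± 131 CPM (SD, n = 3 each; edgeR adjusted p = 0.0041). Gata2, a transcription factor of progenitors and mast cells, went from 384 ± 46.5 to 660 ± 79.4 CPM, and the transcription factor Myb from 354 ± 8.52 to 516 ± 51.8 CPM (edgeR adjusted p = 0.011 and 0.014), calls that were lost for both without vehicle library 2 or 4 (0.055 to 0.070) and for Myb without vehicle library 3 (0.054). Hlf, a transcription factor of stem cells, was the member that fell and is named after its value was seen. Kit, the stem cell factor receptor, was at 216 ± 5.49 and 238 ± 79.0 CPM and did not pass (edgeR adjusted p = 0.68). Camera called the list higher (adjusted p = 0.0089; adjusted p = 0.44 with an estimated correlation).

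Red cell and platelet genes rose. Of 17 tested erythroid genes 11 rose, and 13 were higher and 1 lower when adjusted over the list alone. Hbb-bs, an adult beta-globin, went from 631 ± 166 to 4609 ± 1714 CPM (SD, n = 3 each; edgeR adjusted p = 0.0041), although reads of the adult globin copies cannot be assigned to one copy with certainty. Camera called the list (adjusted p = 5.4e-6; adjusted p = 0.44 with an estimated correlation), with 4 members called without any 1 of vehicle libraries 2, 3 and 4 and 6 without panobinostat library 6. All 11 called members were highest in panobinostat library 1. Hemoglobin genes took 0.744 ± 0.119% of counts in vehicle and 4.55 ± 1.89% with panobinostat (SD, n = 3 each), a difference with a 2-sided exact permutation p of 0.1, the smallest that 3 against 3 can give. Of 9 tested megakaryocyte and platelet genes 6 rose, and 8 passed when adjusted over the list alone. Itga2b, the platelet integrin CD41, and Pf4, platelet factor 4, were 6.15-fold and 5.86-fold higher (edgeR adjusted p = 0.0043 for both), and 5 of the 6 called genes changed most in panobinostat library 5. Camera called that list (adjusted p = 3.1e-4; adjusted p = 0.44 with an estimated correlation).

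**Figure D3:**
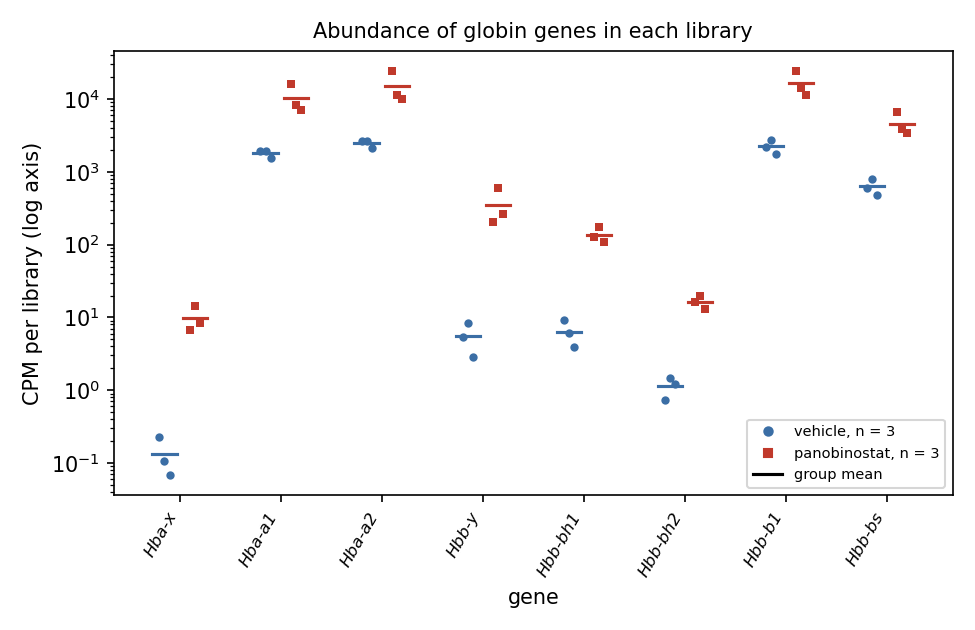
CPM per library on a log axis for 8 alpha-like and beta-like globin genes, with vehicle libraries as blue circles, panobinostat libraries as red squares (n = 3 each, libraries in column order from left to right) and bars at the group means. Panobinostat library 1 is the highest of all for adult Hba-a2, at 24038 CPM, whereas panobinostat library 5 is the highest for embryonic Hbb-y, at 596 CPM.

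Hdac1 was at 184 ± 7.40 and 179.6 ± 12.8 CPM and Hdac3 at 83.1 ± 4.57 and 72.2 ± 5.03 CPM (SD, n = 3 each), and neither passed edgeR's quasi-likelihood test (adjusted p = 0.79 and 0.15). Hdac2 and Hdac6 fell by 0.39 and by 0.60 on the log2 scale (edgeR adjusted p = 0.022 and 0.019), calls that were lost without any 1 of the 3 vehicle libraries (0.055 to 0.11) and for Hdac2 without panobinostat library 5 (0.057). Hdac3 passed with library size alone (0.044) and without panobinostat library 1 (0.044). The class IIa gene Hdac7 rose by 0.72 ± 0.10 (SE; edgeR adjusted p = 0.0068). Of 19 tested histone deacetylase and acetyltransferase genes 1 rose and 3 fell, the same numbers as when adjusted over the list alone, and the list was not called (camera adjusted p = 0.27).

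Genes known to rise with histone deacetylase inhibitors held 4 called members of 14 tested, with 4 when adjusted over the list alone. Txnip, an inhibitor of thioredoxin, went from 639 ± 141 to 1568 ± 91.5 CPM and Tubb3, a neuronal tubulin, from 5.11 ± 2.75 to 30.7 ± 8.08 CPM (SD, n = 3 each; edgeR adjusted p = 0.0054 and 0.0075). The list as a whole was not called (camera adjusted p = 0.11; 0.041 without vehicle library 3). Of 35 neuronal genes listed as held low by the repressor REST, 12 were abundant enough to test. Of these 12, 6 rose, with 6 when adjusted over the list alone. The untested genes stayed near the floor in both groups. Syt4, Snap25, Nefm, Gad1 and Bdnf had 0 counts, and the most abundant, Dnm1, had 51 counts over all libraries. Olfm1, an olfactomedin secreted by neurons, was already at 229 ± 15.4 CPM in vehicle and rose by 0.84 ± 0.10 (log2, SE; edgeR adjusted p = 0.0047). Unc13a, a vesicle priming factor, rose from 0.453 ± 0.143 to 1.52 ± 0.238 CPM. Unc13a missed the threshold without vehicle library 2 (edgeR adjusted p = 0.064) or 3 (0.055). Camera called this list (adjusted p = 0.0089; adjusted p = 0.44 with an estimated correlation).

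Metabolic and stress lists gave mixed results. Of 21 tested glycolysis genes 2 rose and 5 fell, and 2 were higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.097; 0.041 without vehicle library 2 and 0.032 without panobinostat library 5). Tpi1 and Pgam1, enzymes of glycolysis, fell by 0.68 and by 0.54 on the log2 scale (edgeR adjusted p = 0.0066 and 0.018), the latter call being lost without any 1 vehicle library (0.052 to 0.074). Of 23 tested sterol synthesis genes 1 rose and 2 fell, with 0 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.25; 0.032 without panobinostat library 5). Acat2 and Dhcr7, which act early and late in the pathway, were 1.51-fold and 1.39-fold lower (edgeR adjusted p = 0.010 and 0.021); both calls were lost without vehicle library 4 (0.062 and 0.080), and that of Dhcr7 without vehicle library 2 (0.069) or panobinostat library 6 (0.051). Histone genes held 17 tested members, of which 2 fell over all genes and when adjusted over the list alone (camera adjusted p = 0.092; 0.026 without panobinostat library 1, 0.014 without vehicle library 3 and 0.021 without vehicle library 4); they were the histone variants H2az1 and H2ax, named after their values were seen. Of 22 tested heat shock genes 1 rose and 1 fell, Dnajb4 and Fkbp4, named after their values were seen, and 0 passed when adjusted over the list alone. The heat shock list was called lower by camera (adjusted p = 0.014; adjusted p = 0.70 with an estimated correlation), and the call was lost without vehicle library 4 (adjusted p = 0.18). Its inducible member Hspa1a was at 19.6, 285 and 698 CPM in vehicle libraries 2, 3 and 4. Of 16 tested immediate early genes Btg2 rose and Dusp2, named after its value was seen, fell, with 1 higher when adjusted over the list alone (camera adjusted p = 0.14; 4.5e-4 without vehicle library 2).

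The genes of the driver construct did not pass the test. Runx1 was at 667 ± 68.7 and 737 ± 301 CPM, Runx1t1 at 358 ± 72.5 and 615 ± 245 CPM and Nras at 964 ± 63.3 and 1472 ± 462 CPM (SD, n = 3 each; edgeR adjusted p = 0.75, 0.10 and 0.090). Runx1t1 and Nras were called higher without panobinostat library 1 (0.011 and 0.0049) and by DESeq2 (0.033 and 0.036). Reads of an introduced construct and of the mouse genes cannot be told apart in these counts.

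Of 20 T cell markers 2 were abundant enough to test and of 12 natural killer cell markers 0. B cell and plasma cell markers held 13 tested and 0 called genes over all genes and when adjusted over the list alone in edgeR, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.56), and plasmacytoid dendritic cell markers 6 tested and 0 called by both counts, with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.75). DESeq2 and limma-voom also called 0 of either list and 0 of the 2 T cell markers. Of 8 tested conventional dendritic cell markers 2 rose and 3 fell, the same numbers as when adjusted over the list alone (camera adjusted p = 0.56). Clec10a, a lectin receptor, fell from 3.54 ± 1.11 to 0.738 ± 0.131 CPM and Zbtb46, a dendritic cell transcription factor, rose from 8.92 ± 1.27 to 17.4 ± 2.14 CPM (SD, n = 3 each; edgeR adjusted p = 0.0074 and 0.011), and Zbtb46 missed the threshold without vehicle library 4 (0.061). All 13 tested red pulp macrophage markers had a positive log2 fold change (median 1.29), and 2 rose, Hmox1 and Vcam1, named after their values were seen, with 2 when adjusted over the list alone. That list was called by camera (adjusted p = 0.018; adjusted p = 0.70 with an estimated correlation), and the call was lost without panobinostat library 1 (adjusted p = 0.22). Of 12 tested mast cell and basophil markers Gata2 alone rose, as it did when adjusted over the list alone (camera adjusted p = 0.53), and without panobinostat library 1 the list was called higher (adjusted p = 0.011). Of 3 tested endothelial and stromal markers Kdr and Pdgfrb rose, named after their values were seen, with 2 when adjusted over the list alone (camera adjusted p = 0.060; 0.041 without vehicle library 3 and 0.032 without panobinostat library 5).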

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

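No paired analysis was possible because the count columns carry no replicate numbers that the labels explain, so the block by replicate was not run. Vehicle libraries 2 and 3 share a code of unknown meaning, and panobinostat libraries 1 and 6 share part of theirs, so their independence is open. The fit without globin genes was chosen after seeing the data. With 3 libraries per group, single libraries set much of the number of calls. Leaving out 1 library gave 438 (vehicle library 4) to 4056 (panobinostat library 1) genes, 303 to 2192 higher, 135 to 1864 lower and 307 to 1031 with a change of at least 2-fold, at the same ends. In these fits a group has 2 libraries, and what else lowered the count without vehicle libraries 2 or 4 was not tested. Limma-voom with sample quality weights called 4520 genes, 2358 higher and 2162 lower, and library size alone called 2065 lower genes, both for causes that were not tested. DESeq2 called 3529 genes, limma-voom 2641, robust shrinkage 2706, RLE factors 2704, upper-quartile factors 2711, no filter 2564, the stricter filter 2632 and the fit without globin genes 2707. No gene called here was called in the opposite direction in any of these fits, and 2689 of the 2715 calls were shared with DESeq2.

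All 7 called primary lists kept their direction and were called in each of the 6 fits with a library left out, with library size alone and with the stricter filter. With an estimated correlation none was called, and the adjusted p was 0.44 for type I interferon-stimulated genes, MHC class I presentation, monocyte and macrophage, stem and progenitor, proliferation, ribosome biogenesis and REST-repressed neuronal genes. The fry test also missed the threshold for monocyte and macrophage genes (adjusted p = 0.058) and for stem and progenitor genes (adjusted p = 0.057), and among the other called lists for erythroid (0.057), p53 target (0.070), MHC class II (0.088), heat shock (0.33) and red pulp macrophage genes (0.33). Of 1338 comparisons of 84 named genes across 16 settings, 1248 kept their side of the threshold, 78 missed it and 12 newly passed it. Genes called in the main fit reversed direction in 0 comparisons, and reversals of genes not called were not counted. Genes chosen after their values were seen were not part of these comparisons. Depth limited genes near the floor, where a CPM under 0.1 rests on fewer than 5 counts.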

Other observations

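In this part, the tests on cell admixture and on globins were chosen after the results were seen. The count of other splits and the test on gene positions were set before. CPM of admixture markers were scaled over all counted genes, so they differ slightly from those of tested genes.

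Some genes that rose with panobinostat lay together on chromosomes. Of 752 windows of 2 Mb with enough tested genes, 9 held more called-higher genes than their tested genes would give by chance (hypergeometric test, Benjamini-Hochberg adjusted p under 0.05), with 11.5% of the tested genes that have a position called higher. These windows held 117 of the 1460 genes called higher. The hypothesis that clusters of related genes rose together predicted passing windows, and 9 passed. The test counts positions and does not measure whether genes are related, so it cannot decide that hypothesis. The clearest window was on GRCm38 chromosome 7, from 104000001 to 106000000, with 15 of 27 genes higher (adjusted p = 2.7e-05), among them Trim5, Trim6, Trim12a, Trim12c, Trim30a, Trim30b, Trim30d, Trim34a and Trim34b, which encode antiviral TRIM proteins. On chromosome 17, from 36000001 to 38000000, 13 of 22 genes were higher (adjusted p = 4.1e-05), most of them class I genes such as H2-T3, H2-T10, H2-T22, H2-T23 and H2-T24. The Oas genes on chromosome 5, the Ifit genes on chromosome 19, Phf11 genes on chromosome 14 and Sp100, Sp110 and Sp140 on chromosome 1 filled other such windows (adjusted p = 4.3e-04, 0.0044, 0.0066 and 0.037). Copies in such clusters can share reads, so the members are not independent.

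The 5 genes of this paragraph were chosen after their values were seen. Cd274, which encodes PD-L1, went from 38.9 ± 7.02 to 117 ± 33.2 CPM (SD, n = 3 each), Pdcd1lg2, which encodes PD-L2, from 5.84 ± 1.82 to 15.8 ± 5.66 CPM, and the costimulatory gene Cd80 from 2.99 ± 1.29 to 23.7 ± 10.5 CPM (edgeR adjusted p = 0.0062, 0.021 and 0.0063). Csf2rb, which encodes the shared chain of the IL-3, IL-5 and GM-CSF receptors, and the similar gene Csf2rb2 rose by 1.46 ± 0.30 and 1.86 ± 0.39 on the log2 scale (SE; edgeR adjusted p = 0.018 and 0.019).

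The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The grouping by treatment called 2715 genes, 1460 higher, 1255 lower and 830 with a change of at least 2-fold, and the highest of the other splits called 0 in each case by edgeR, so 1 of 10 splits gave a result as large. In the other splits the treatment difference lies within both sides and widens their spread, so few calls were likely from the start. Their 0 calls cannot show how many genes a grouping of like libraries would call. The other splits held from 25 to 968 genes at an unadjusted p under 0.05, against 4752, and limma-voom called 0 in each of them. For camera with the preset correlation the result was different. The grouping by treatment called 15 lists and the highest of the other splits 18, with 3 of 10 splits calling as many. Other splits called from 10 lists upward, but each mixes the treatments unevenly and so still carries part of the treatment difference. These splits therefore cannot decide whether a camera call alone singles out the treatment. Of the 15 called lists 3 had their smallest p in the treatment grouping. By the adjusted p of limma's camera they were type I interferon-stimulated genes (2.7e-27, against 2.8e-14 in the closest other split), interferon-inducible GTPases (2.3e-10 against 6.2e-06) and stem and progenitor genes (0.0089 against 0.016).

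Interferon-stimulated RNA rose by 5159 CPM summed over the 43 called genes, and RNA of immune cells carried into the sort is a possible explanation; a first, narrower marker set lay under a bound of 5% of that increase, but all 164 immune markers together reached 15.7%, above it, and the markers were then separated by cell type, counting rising markers alone for the lymphoid, dendritic and red pulp sets. Of 75 lymphocyte and dendritic cell markers 42 rose in mean, by 19.2 CPM in sum or 0.372%, under the bound. The most abundant of these markers in vehicle and panobinostat included Cst3 (43.5 and 43.8 CPM), Naaa (17.6 and 8.69 CPM), Lair1 (14.2 and 10.9 CPM) and Zbtb46, which rose (8.97 and 17.3 CPM). The 75 leave out the MHC class II genes, which are among the 164 and were called higher by camera (adjusted p = 0.0089; 0.098 without panobinostat library 1). How much marker RNA such cells hold beside interferon-stimulated RNA was not measured, so lymphocytes and dendritic cells as a source stay open. Red pulp macrophages cannot be told apart from a change in the leukemia cells, since all 16 of their markers were higher in mean (35.9 CPM in sum or 0.696%; Hmox1 3.71 and 16.8 CPM, Axl 8.57 and 11.6 CPM, Slc40a1 3.31 and 8.57 CPM). Nor can monocytes or granulocytes, whose 62 genes rose by 759 CPM or 14.7%, mostly through Hdc, Ctsd and Ctsb, which vehicle cells already held above 300 CPM. Of these, Hdc was not called (edgeR adjusted p = 0.42). In panobinostat library 1 Hdc was below every vehicle library (912 against 1130 to 1334 CPM, scaled over tested genes). The 55 genes under 5 CPM in vehicle gave 0.253%. The 7 secretory transcripts Lyz2, S100a8, S100a9, Ngp, Camp, Ltf and Lcn2 went from 9.63 ± 3.97 to 7.70 ± 2.87 CPM in sum. This weighs against a large share but excludes nothing, as these 7 were picked after their values were seen and leave out called genes. The sort for GFP was meant to remove such cells, but its purity was not tested here. A response of the leukemia cells is a hypothesis, and whether interferon acted on the leukemia cells was not tested.

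Embryonic globin genes, extended after the values were seen to Hba-x and Hbb-bh2, were among the genes with large increases (log2 fold change 6.14 ± 0.48 and 3.84 ± 0.29, SE, n = 3 each; edgeR adjusted p = 0.0016 and 0.0014). Hbb-y and Hbb-bh1 made up 0.510%, 0.405% and 0.303% of beta-like globin counts in vehicle libraries 2, 3 and 4, and 1.05%, 4.09% and 2.41% in panobinostat libraries 1, 5 and 6 (95% exact binomial intervals, for counting error only, from 0.262% to 0.560% and from 1.03% to 4.15% over the libraries). Carried-over adult red cells or misassigned adult globin reads would hold this share level, yet the lowest panobinostat share was 2.07 times the highest vehicle share, which argues against each as the whole source of the embryonic part. For the adult globins and the erythroid list (median log2 fold change 1.02), red cells of the spleen and a shift of the leukemia cells cannot be told apart, because vehicle leukemia cells held all 17 erythroid markers above 1 CPM. A response of normal erythroid cells to the drug also stays open, although the GFP sort was meant to remove them.

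The panobinostat libraries differed in red cell and mast cell markers. Relative to the vehicle mean, the median log2 difference of mast cell and basophil markers was -0.96 in panobinostat library 1, 1.30 in library 5 and 0.41 in library 6, while that of erythroid markers was 1.62, 0.34 and 0.78. Cpa3, a mast cell protease, was at 13.7, 312 and 147 CPM in panobinostat libraries 1, 5 and 6. What lies behind this difference stays open.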
